A study of Arabidopsis thaliana with 30 samples.

How the data were processed

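RNA from whole seedlings without roots was measured on 30 Affymetrix ATH1 arrays, 3 biological replicates for each of 5 lines at each of 2 times. RNA was extracted with the NucleoSpin RNA Plant kit and labelled with the NuGEN Encore Biotin Module, per the labels' protocols. The deposited values are log2 signal after RMA in the affy package, per the submitters' processing notes, and their versions are not given in the sources used here. Whether all 30 arrays were normalized together, and whether the 0 h harvest came before or after the dark period, are also not given in the sources used here. Raw scans and detection calls were not used here.

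Of 22810 probe sets 64 were controls, and the other 22746 were tested. By the annotation held, 13513 were matched to exactly 1 gene, 503 to several and 8730 to none, and only the first kind is named by gene. A gene with more than 1 probe set, which held for 147 genes, was represented in lists by the probe set with the highest mean over the 30 arrays. Array means lay between 6.70 and 6.77 except for mbs1-1 3 h replicate 1 (6.96) and wild type 0 h replicate 1 (6.88). Within groups the correlation of arrays ran from 0.983 to 0.996, no pair of arrays was identical, and the median residual SD was 0.200 on the log2 scale. The first principal component held 68.5% of the variance and the second 8.87%. The 3' minus 5' signal of the actin controls was 6.04 to 6.39 in wild type at 0 h, 6.61 to 6.82 at 3 h and 6.93 to 6.98 in flu at 3 h. That of the GAPDH controls overlapped, at 3.30 to 3.79, 3.42 to 3.62 and 3.29 to 3.79. The 25S rRNA signal was 5.02 to 5.17 in wild type at 0 h and 4.18 to 4.48 at 3 h. Whether RNA quality bears on the calls was not tested.

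Groups followed the labels. A linear model with 10 group means was fitted to all 30 arrays with limma 3.58.1 in R 4.3.3, with moderated variances and Benjamini-Hochberg adjustment over all tested probe sets. Probe sets with an adjusted p under 0.05 were called, and those with an absolute log2 fold change of at least 1 were counted as well. The 19 comparisons were 3 h against 0 h in each line, each line against wild type at each time, RNAi-MBS2/mbs1-1 against mbs1-1 at each time, and the difference of each line's response from that of wild type. Python 3.11.15 and matplotlib 3.10.9 were used for tables and plots.

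Gene lists were tested with limma's camera at a preset correlation between genes of 0.01 and again with the correlation estimated from the data, adjusted within each comparison and family of lists. The 20 lists fixed before the data were examined hold 326 genes, of which 61 were matched, and only the 9 lists with at least 3 measured genes were tested. The adjustment was therefore over 9 lists and not over the 20 planned. Some tested lists were only partly measured, with 3 of 21 light-harvesting antenna genes, 3 of 17 abscisic acid and cold genes and 4 of 15 singlet oxygen genes. Their names stand for these few genes only. A further 20 lists were put together from the genes that the annotation was seen to name, before any comparison was computed, and 19 of them were tested. With an estimated correlation 1 of the 33 fixed-list calls held, hydrogen peroxide and antioxidant genes in mbs1-1 at 0 h, and 3 of the 73 added-list calls, endoplasmic reticulum stress in flu at 3 h and both that list and late embryogenesis and cold in the difference of the flu response. The median, mean and test had one direction in each of the 106 list calls.

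The lists, the comparisons, the test, the rule for naming genes and all alternatives but 2 were chosen before the data were examined. By that rule the text names MBS1, MBS2 and FLU, up to 4 members with the largest called change of each described fixed list, or the 1 with the smallest p if none was called, the singlet oxygen markers AT3G28580 and BAP1, and the 5 highest and 5 lowest called genes of each comparison. For the differences of responses and for RNAi-MBS2/mbs1-1 against mbs1-1 the 3 highest and 3 lowest were taken. Genes of a comparison between groups had to have groups without overlap. Members of added lists and of lists too small to test were chosen after their values were seen.

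The alternatives were a fit to the compared arrays alone, a block for the replicate number, leaving out probe sets with a mean under 5, quantile normalization, centring each array on its median, a trended and robust variance prior, only probe sets with exactly 1 gene, an estimated correlation, a list test on gene means, and each array left out in turn. Both brighter arrays left out, and the flu 0 h array with the widest spread left out, were added after seeing the data. The calls were also counted in other splits of the same arrays, all 10 for a pair of groups and 100 drawn for a difference of responses.

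The steps were tested on simulated data with each probe set's real mean and spread, drawn independently of the other probe sets. Only 50 probe sets were changed by each size, far fewer than were called in flu at 3 h, and the share recovered depends on that number. For flu against wild type at 3 h, 26% of probe sets changed by 0.5 were recovered, 92% of those changed by 1, 100% of those changed by 2 and 98% of those changed by 3, with 9 false calls among 22746 probe sets. For the response in flu the shares were 30%, 90%, 98% and 98% with 16 false calls, and for the difference of the flu response 8%, 66%, 98% and 98% with 6. An unchanged mbs1-1 against wild type at 3 h gave 0 false calls in limma, a list of 20 probe sets raised by 0.5 was called, and 0 of 100 unchanged lists were. Since the simulated probe sets were not correlated, this gives no rate of false list calls for correlated genes.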

Results

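Transcript levels were measured on 30 Arabidopsis genome arrays, 3 biological replicates in each of 10 groups. The groups were 5 lines sampled at 2 times. Wild type was Col-0, the strain also given for the other lines. The flu line carries a mutation in FLU, a repressor of chlorophyll synthesis in the dark, and its plants gather protochlorophyllide, which gives singlet oxygen once light returns. The mbs1-1 line is a mutant of MBS1, a small zinc-finger protein, RNAi-MBS2/mbs1-1 adds RNA interference against the related gene MBS2, and 35S:MBS1 overexpresses MBS1. Seedlings without roots were taken at an age of 12 days, after 7 days of adaptation to a photon flux of 10 µE per square metre and second. The 0 h groups had no high light, and the 3 h groups had 3 h at 1000 µE per square metre and second after 3 h of darkness, so that darkness and high light are not separated in a 3 h against 0 h comparison. Whether both were harvested at the same time of day is not known here, so changes with the clock are not separated either. The number of arrays, 3 per group, limits the precision of each value. Levels are given as log2 values ± SD and differences as log2 fold changes ± SE, always with n = 3 arrays per group. Adjusted p-values of genes are limma's and those of gene lists come from its camera test. Genes given as highest or lowest were ranked only among probe sets matched to exactly 1 gene, and unnamed probe sets can lie beyond them. The genes so given between 2 groups had all 3 arrays of one group above all 3 of the other, which chance gives to 10% of genes.

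No probe set was matched to MBS1, MBS2, FLU or the singlet oxygen marker BAP1 alone, so the targeted genes give no check of the labels here. One unnamed probe set, probe-258623_at, chosen after its values were seen, was the only one of 22746 that was lower than wild type in both mbs1-1 lines and higher in 35S:MBS1 at both times. Its level was 9.05 ± 0.09 in wild type at 0 h, 4.44 ± 0.33 in mbs1-1, 5.05 ± 0.62 in RNAi-MBS2/mbs1-1, 13.82 ± 0.17 in 35S:MBS1 and 9.29 ± 0.33 in flu. At 3 h the levels were 8.75 ± 0.01, 4.41 ± 0.37, 3.96 ± 0.15 and 13.43 ± 0.11 in the first 4 of these, and flu differed from wild type by 0.25 ± 0.22 without passing. Its differences from wild type at 3 h were -4.34, -4.79 and 4.68 (SE 0.22 each) in mbs1-1, RNAi-MBS2/mbs1-1 and 35S:MBS1, with adjusted p of 1.7e-12, 1.61e-13 and 2.73e-13. Whether its signal in both mbs1-1 lines lay above background was not tested, so the size of the lower differences is uncertain. AT3G28580, an AAA-type ATPase gene used as a marker of singlet oxygen, passed no comparison over all probe sets. With adjustment over the singlet oxygen list alone it passed in flu against wild type at 3 h. Its level at 3 h was 5.90 ± 0.58 in flu and 4.74 ± 0.29 in wild type, a difference of 1.16 ± 0.46 (adjusted p = 0.0853).

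The first question was what the step to high light changed in wild type. AT2G23910, a gene for a NAD(P)-binding protein, rose by 6.22 ± 0.16 (adjusted p = 4.61e-20), from 4.83 ± 0.16 to 11.05 ± 0.04. The cysteine protease gene AT2G27420, the flavonol rhamnosyltransferase gene AT1G06000, the DnaJ-type chaperone gene AT1G71000 and AT3G44450, which encodes an inhibitor of cryptochrome, rose by 5.45 ± 0.19, 5.28 ± 0.31, 4.99 ± 0.34 and 4.98 ± 0.22. AT4G27450 and IAA29, the latter an auxin-response repressor of shaded and elongating tissue, had log2 fold changes of -6.65 ± 0.37 and -5.83 ± 0.35. AT3G29970 (-6.26 ± 1.39), AT2G17850 (-5.73 ± 1.096) and the glutaredoxin gene AT3G62950 (-5.50 ± 0.35) also fell.

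Among the fixed lists, 4 of the 5 measured flavonoid and anthocyanin genes rose in wild type, and 4 with adjustment over the list alone. They were UGT78D2 (3.36 ± 0.11) and AT4G14090 (1.13 ± 0.20), which attach sugars to flavonoids and anthocyanins, dihydroflavonol reductase DFR (1.68 ± 0.38) and UF3GT (0.64 ± 0.19). The list passed at an adjusted p of 0.00941, with an adjusted p of 0.171 when the correlation was estimated. Of 8 tetrapyrrole synthesis genes 6 fell, also 6 adjusted over the list alone, led by the chlorophyll synthesis genes PORB (-1.85 ± 0.19) and CHLM (-1.28 ± 0.16) and followed by HEMB1 (-0.67 ± 0.11) and HEME2 (-0.61 ± 0.16). The list test gave an adjusted p of 0.0204, and an adjusted p of 0.232 with an estimated correlation. The cold-regulated chloroplast protein genes COR15B (4.86 ± 0.34) and COR15A (4.37 ± 0.33) were the 2 of 3 measured abscisic acid and cold genes that rose, also 2 adjusted over the list alone, while COR47 stood at -0.05 ± 0.20 (list adjusted p = 0.0204, and adjusted p = 0.232 with an estimated correlation). In the lists added later, 9 of 10 ATG8-type autophagy genes fell, with ATG8E at -4.32 ± 0.23 (adjusted p = 4.55e-05, and adjusted p = 0.495 with an estimated correlation). Of 21 genes for plastid gene expression 14 fell (adjusted p = 0.00315, estimated correlation adjusted p = 0.745), and of 19 heat shock genes 11 rose and 3 fell (0.00315 and 0.727). In all, 10345 of 22746 probe sets passed, 4791 higher (46.3%) and 5554 lower, and 3801 of them by at least 1 on the log2 scale. Higher calls were 50.8% without wild type 0 h replicate 1 and 50.6% with both brighter arrays left out, so that which direction held more was not settled.

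The other lines went through the same step. In flu, AT1G71000 rose by 6.59 ± 0.34, the dehydrin gene LTI30 by 6.22 ± 0.39, COR15B by 5.84 ± 0.34, COR15A by 5.77 ± 0.33 and the calmodulin-like gene CML37 by 5.60 ± 0.26. The lipid transfer protein gene AT5G48490 (-5.10 ± 0.23), AT3G19850 (-4.99 ± 0.29), IAA29 (-4.93 ± 0.35), AT3G62950 (-4.93 ± 0.35) and AT4G27450 (-4.92 ± 0.37) fell. All 5 measured heat shock chaperone genes rose in flu, with ATHSP22.0 at 4.59 ± 0.77 and AT1G53540 at 3.77 ± 0.95 (list adjusted p = 0.00935, and adjusted p = 0.363 with an estimated correlation). Of 4 singlet oxygen genes 3 rose, CML37, the flotillin-like AT5G64870 (2.64 ± 0.26) and CML38 (2.49 ± 0.31), at a list adjusted p of 0.00387 and an adjusted p of 0.119 with an estimated correlation. Over these lists alone the counts were also 5 and 3. Of 10 nuclear photosynthesis genes, an added list, 8 fell in flu (adjusted p = 0.000706, and adjusted p = 0.285 with an estimated correlation).

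In mbs1-1 the highest changes among named genes were those of AT2G27420 (6.62 ± 0.19), AT2G23910 (6.57 ± 0.16), AT1G71000 (5.93 ± 0.34), AT5G42760 (5.64 ± 0.15) and COR15B (5.53 ± 0.34), and the lowest those of AT3G29970 (-7.02 ± 1.39), IAA29 (-6.55 ± 0.35), AT4G27450 (-6.46 ± 0.37), AT2G17850 (-6.44 ± 1.096) and AT3G15450 (-6.36 ± 0.45), a gene raised in darkness. The median of all probe sets in this line lay at 0.10, and relative to it AT2G27420 stood at 6.52 and AT3G29970 at -7.12. In RNAi-MBS2/mbs1-1, AT2G23910 (6.40 ± 0.16), COR15A (5.69 ± 0.33), AT2G27420 (5.63 ± 0.19), the sinapate glucosyltransferase gene UGT84A1 (5.45 ± 0.14) and COR15B (5.43 ± 0.34) led, against IAA29 (-6.89 ± 0.35), AT5G62280 (-6.11 ± 0.22), AT3G15450 (-5.94 ± 0.45), AT4G27450 (-5.54 ± 0.37) and AT3G62950 (-5.16 ± 0.35). In 35S:MBS1 the highest named genes were AT2G23910 (6.73 ± 0.16), AT2G27420 (6.29 ± 0.19), AT5G42760 (5.44 ± 0.15), AT1G06000 (5.44 ± 0.31) and TBL26 (5.30 ± 0.21), and the lowest AT4G27450 (-6.72 ± 0.37), AT3G15450 (-6.27 ± 0.45), AT2G17850 (-6.20 ± 1.096), IAA29 (-6.07 ± 0.35) and AT3G29970 (-5.65 ± 1.39).

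The abscisic acid and cold list rose and the tetrapyrrole list fell in each of these 4 lines. Of the 3 cold genes, 3 rose in flu (adjusted p = 0.00224), 3 in mbs1-1 (0.0145), 3 in RNAi-MBS2/mbs1-1 (0.00277) and 2 in 35S:MBS1 (0.00871), with adjusted p of 0.119, 0.243, 0.199 and 0.168 when the correlation was estimated. Of the 8 tetrapyrrole genes, 6, 5, 6 and 7 fell in the same order, and HEMA2, which starts this synthesis, rose in flu (0.79 ± 0.14). The list adjusted p were 0.00463, 0.0145, 0.0279 and 0.00754, and 0.119, 0.243, 0.215 and 0.168 as adjusted p with an estimated correlation. Adjusted over the list alone these member counts were the same. CHLM fell by 2.14 ± 0.16 in flu, 0.94 ± 0.16 in mbs1-1, 1.29 ± 0.16 in RNAi-MBS2/mbs1-1 and 1.41 ± 0.16 in 35S:MBS1. The flavonoid list passed in RNAi-MBS2/mbs1-1 with 2 of 5 genes higher, 3 adjusted over the list alone, and in 35S:MBS1 with 3 of 5, also 3 over the list alone (adjusted p = 0.038 and 0.0274, and adjusted p of 0.215 and 0.168 with an estimated correlation). UGT78D2 rose by 3.95 ± 0.11 and 3.79 ± 0.11 in these lines.

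The step to high light moved 10932 probe sets in flu (5222 higher, 5710 lower), 10156 in mbs1-1 (5886 and 4270), 10378 in RNAi-MBS2/mbs1-1 (4814 and 5564) and 10687 in 35S:MBS1 (5010 and 5677). Higher calls were 58.0% in mbs1-1, 49.5% after quantile normalization, 50.3% after centring on the median and 51.9% without its 3 h replicate 1, so that the excess of higher calls there depended on the scaling. In flu they were 47.8%, and 40.1% after centring. A change of at least 1 was found for 4481, 3603, 3481 and 3937 calls in flu, mbs1-1, RNAi-MBS2/mbs1-1 and 35S:MBS1. The calls of COR47 and HEME2 in mbs1-1, and of AT4G14090 in RNAi-MBS2/mbs1-1 and 35S:MBS1, were lost when single arrays were left out, COR47 without replicate 2 at 0 h (adjusted p 0.00549 to 0.0554 over all settings) and HEME2 without replicate 3 at 3 h (0.000311 to 0.0653). AT4G14090 lost its call in RNAi-MBS2/mbs1-1 without 0 h replicate 3 or 3 h replicate 2 (0.014 to 0.113 over all settings), and in 35S:MBS1 without 0 h replicates 2 or 3 or 3 h replicate 3 (0.00869 to 0.0905).

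Before high light, the lines were set against wild type to find what the mutations alone changed. In flu at 0 h, AT3G52070 was 15.3-fold higher (3.93 ± 0.24, adjusted p = 1.31e-10), at 10.16 ± 0.37 against 6.23 ± 0.61 in wild type. AT5G26970 (3.78 ± 0.54), AT4G17470 (2.29 ± 0.29), AT3G16040 (2.24 ± 0.36) and THI2.1, a thionin gene of jasmonate responses (3.87 ± 0.78, adjusted p = 0.0171), were also higher, THI2.1 with a wide spread in flu (7.11 ± 3.08). The sizes of THI2.1, AT5G26970 and AT3G16040 moved by over 1.5-fold with single flu 0 h arrays left out. AT2G14230 (-3.14 ± 0.39), the late embryogenesis gene M17 (-2.39 ± 0.49), AT5G20790 (-2.09 ± 0.47) and 2 genes of the iron deficiency response, BHLH101 (-2.30 ± 0.49) and AT1G47400 (-2.05 ± 0.37), were lower. No fixed list passed in this comparison. Of the lists added later, jasmonate and wound genes stood higher, with a median of 0.0075 and 1 gene called, THI2.1. Cell wall loosening and mitosis genes stood lower, with no member called. None of these list calls held with an estimated correlation.

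At 0 h 115 probe sets differed between flu and wild type, 47 higher and 68 lower, 57 of them by at least 1. Higher calls made up 40.9% of these, 52.5% after quantile normalization and 58.3% after centring each array on its median. The count was 52 without wild type 0 h replicate 1 and 70 without wild type 0 h replicate 3. Over all settings the adjusted p of THI2.1 ran from 9.26e-09 to 0.684, of BHLH101 from 0.0178 to 0.216, of M17 from 0.00408 to 0.22 and of AT5G20790 from 0.0139 to 0.251. Their calls were lost with several single arrays left out, THI2.1 without flu 0 h replicates 1 or 2 or wild type 0 h replicates 1 or 3. BHLH101 lost its call without any flu array or wild type replicates 2 or 3, M17 without flu replicates 1 or 3 or wild type replicates 1 or 2, and AT5G20790 without any 1 of the 6 arrays. With only the compared arrays in the fit 8 calls were left, and AT4G17470 (5.87e-05 to 0.134 over all settings), AT5G26970 (4.29e-09 to 0.367), AT3G16040 (2.44e-06 to 0.367) and AT1G47400 (0.000716 to 0.231) lost theirs in that fit alone.

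Few probe sets were called between the lines with altered MBS1 and wild type at 0 h. In limma 1908 in mbs1-1, 1688 in RNAi-MBS2/mbs1-1 and 879 in 35S:MBS1 had an unadjusted p under 0.05, where 1137 would be expected by chance. Smaller differences may thus be present in the mbs1-1 lines. AT3G52070 was higher in all 3 lines, by 3.62 ± 0.24 in mbs1-1, 3.55 ± 0.24 in RNAi-MBS2/mbs1-1 and 3.91 ± 0.24 in 35S:MBS1 (adjusted p of 4.48e-10, 6.73e-10 and 7.57e-11). AT1G62250 was lower in mbs1-1 (-1.31 ± 0.16, adjusted p = 9.39e-05). In RNAi-MBS2/mbs1-1, which carries the same mutation, its arrays read 10.08 to 10.21 at 0 h, against 9.82 to 10.04 in wild type. The lower level was thus not shared by both lines without MBS1. In RNAi-MBS2/mbs1-1, AT5G37450, a receptor-like kinase gene, was higher (1.48 ± 0.20, adjusted p = 0.000445) and AT2G19970 lower (-1.59 ± 0.25, adjusted p = 0.0049). In 35S:MBS1, AT2G13550 was higher (1.11 ± 0.19, adjusted p = 0.0303).

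The counts at 0 h were 7 probe sets in mbs1-1 (3 higher, 4 lower), 7 in RNAi-MBS2/mbs1-1 (4 and 3) and 4 in 35S:MBS1 (3 and 1). The lower one there was probe-266550_s_at, which has no single gene and was chosen after its values were seen (-1.15 ± 0.20, adjusted p = 0.0329). It lost its call when each array was centred on its median, leaving 100% of calls higher, and without 35S:MBS1 replicates 1 or 3 or wild type replicates 1 or 3 (0.000403 to 0.999 over all settings). The count in RNAi-MBS2/mbs1-1 became 66 without its replicate 3 and 31 without wild type replicate 3, and that in 35S:MBS1 became 2 without its replicates 1 or 3 or without wild type replicate 1. AT2G19970 lost its call without RNAi-MBS2/mbs1-1 replicate 1 or wild type replicate 1 (adjusted p 0.00055 to 0.413 over all settings), and AT2G13550 without any 1 of the 6 arrays compared (0.00863 to 0.34). AT1G62250 in mbs1-1 (1.02e-05 to 0.0533) and AT5G37450 in RNAi-MBS2/mbs1-1 (2.64e-05 to 0.413) lost their calls only with the compared arrays alone in the fit.

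Hydrogen peroxide and antioxidant genes passed as a list in mbs1-1 at 0 h (adjusted p = 0.0106, and adjusted p = 0.0486 with an estimated correlation), although none of the 7 passed over all probe sets and 1 did adjusted over the list alone, the ascorbate peroxidase gene SAPX at 0.91 ± 0.23. The heat shock chaperone list stood higher in RNAi-MBS2/mbs1-1 than in wild type (adjusted p = 1.63e-05, and adjusted p = 0.225 with an estimated correlation). None of its 5 genes passed over all probe sets and 3 did over the list alone, and the immunophilin gene AT5G48570 had a value of 1.77 ± 0.45. At 0 h RNAi-MBS2/mbs1-1 differed from mbs1-1 in 1 probe set, that of AT1G62250 (1.56 ± 0.16, adjusted p = 1.3e-05, and 8.57e-07 to 0.0897 over all settings, lost only with the compared arrays alone). Higher calls were 100%, and 66.7% of 3 after quantile normalization. That count was 2 without mbs1-1 0 h replicate 3 or RNAi-MBS2/mbs1-1 0 h replicate 2 and 15 without RNAi-MBS2/mbs1-1 0 h replicate 3. The heat shock chaperone list passed there as well (adjusted p = 0.00451, and adjusted p = 0.417 with an estimated correlation), with 0 of 5 genes past limma's test over all probe sets or over the list alone, and 1997 probe sets at an unadjusted p under 0.05 in that comparison.

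After 3 h of high light flu differed most from wild type. The small heat shock protein gene AT1G52560 was higher in flu by 6.24 ± 0.59 (adjusted p = 3.97e-08), at 10.60 ± 0.79 against 4.36 ± 0.14, and whether the wild type signal lay above background was not tested. JRG21 (5.48 ± 0.54) and AT2G38240 (5.45 ± 0.53), which encode jasmonate-regulated oxygenases, ATHSP22.0, a small heat shock protein of the endoplasmic reticulum (4.64 ± 0.77), and AT5G24240 (4.21 ± 0.60) followed. The sugar transporter gene AT5G18840 was lowest (-2.70 ± 0.32, adjusted p = 1.19e-06), with AT3G44510 (-2.31 ± 0.44), AT5G61590, a transcription factor gene that limits wax synthesis (-2.29 ± 0.26), the cytochrome P450 gene CYP71B36 (-2.14 ± 0.26) and AT4G16563 (-2.11 ± 0.24). Of 22746 probe sets 4164 passed, 1970 higher and 2194 lower, and 787 of the higher ones and 215 of the lower ones changed by at least 1. Which direction held more calls depended on single arrays. The share of higher ones was 47.3%, and it was 52.3% and 56.3% without flu 3 h replicates 1 and 3 and 50.9% and 52.5% without wild type 3 h replicates 1 and 2. The sizes of AT2G38240 and AT3G44510 also moved by over 1.5-fold with 1 array left out.

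Singlet oxygen genes were higher in flu at 3 h. Of 4 measured, 3 passed over all probe sets and 4 adjusted over the list alone. CML37 stood at 10.57 ± 0.29 in flu and 7.47 ± 0.37 in wild type (3.099 ± 0.26), CML38 differed by 1.90 ± 0.31 and AT5G64870 by 0.84 ± 0.26. The list passed at an adjusted p of 5.16e-05, with an adjusted p of 0.0532 when the correlation was estimated. Heat shock chaperone genes were also higher, 3 of 5 over all probe sets and 5 over the list alone, with ATHSP22.0, the peroxisomal small heat shock gene AT5G37670 (3.00 ± 0.43) and HSA32 (2.19 ± 0.23), which acts in heat tolerance after acclimation (list adjusted p = 1.12e-05, and adjusted p = 0.0918 with an estimated correlation). Of 21 light-harvesting antenna genes in the list only 3 were measured, all LHCB4 genes. LHCB4.3 (-1.51 ± 0.17) and LHCB4.2 (-0.60 ± 0.16) were lower and LHCB4.1 stood at -0.02 ± 0.11, so that 2 of 3 fell below wild type, also 2 over the list alone (adjusted p = 0.0301, and adjusted p = 0.0918 with an estimated correlation). Of the 3 abscisic acid and cold genes COR47 passed (0.90 ± 0.20), and 2 did over the list alone (adjusted p = 0.0449, and adjusted p = 0.282 with an estimated correlation). The calls of AT5G64870 and LHCB4.2 were lost with single arrays left out, AT5G64870 without flu 3 h replicate 3 or wild type 3 h replicates 2 or 3 (adjusted p 0.017 to 0.193 over all settings), and LHCB4.2 without flu 3 h replicate 3 (0.00025 to 0.124).

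Several lists added later moved as well in flu at 3 h. Of 13 endoplasmic reticulum stress genes 8 were higher, among them DER1 (1.13 ± 0.14), which acts in the removal of misfolded proteins, the transcription factor genes BZIP28 (1.08 ± 0.15) and BZIP60 (0.72 ± 0.20), and UBC32 (0.55 ± 0.12). This list passed at an adjusted p of 1.24e-06 and kept its call with an estimated correlation (adjusted p = 0.000534). Of 13 jasmonate and wound genes 6 were higher, with JRG21, THI2.1 (4.06 ± 0.78), CML37 and the methyltransferase gene BSMT1 (2.79 ± 0.26), at an adjusted p of 8.36e-05 (adjusted p = 0.0718 with an estimated correlation). That list also stood higher in flu at 0 h, where THI2.1 was about as far above wild type already. In the difference of the flu response the list passed as well, with 4 genes called higher. Of 12 late embryogenesis and cold genes 5 were higher and 1 lower, with LTI30 (2.71 ± 0.39), LEA4-5 (1.91 ± 0.40) and LEA18 (1.90 ± 0.33) highest (adjusted p = 8.04e-05, and adjusted p = 0.0659 with an estimated correlation). Of 19 genes of the longer heat shock list 12 were higher and 1 lower (adjusted p = 3.62e-11, and adjusted p = 0.103 with an estimated correlation). Of 10 nuclear photosynthesis genes 6 were lower, including the Calvin cycle genes PRK (-0.74 ± 0.14) and RCA (-0.62 ± 0.11) and the calcium sensor gene CaS (-0.65 ± 0.11), at an adjusted p of 3.81e-05 (adjusted p = 0.164 with an estimated correlation). BZIP60 lost its call without flu 3 h replicate 3 or wild type 3 h replicate 3 (adjusted p 0.00853 to 0.0849 over all settings), and LEA4-5 only with the compared arrays alone in the fit (1.14e-07 to 0.0707).

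**Figure D1:**
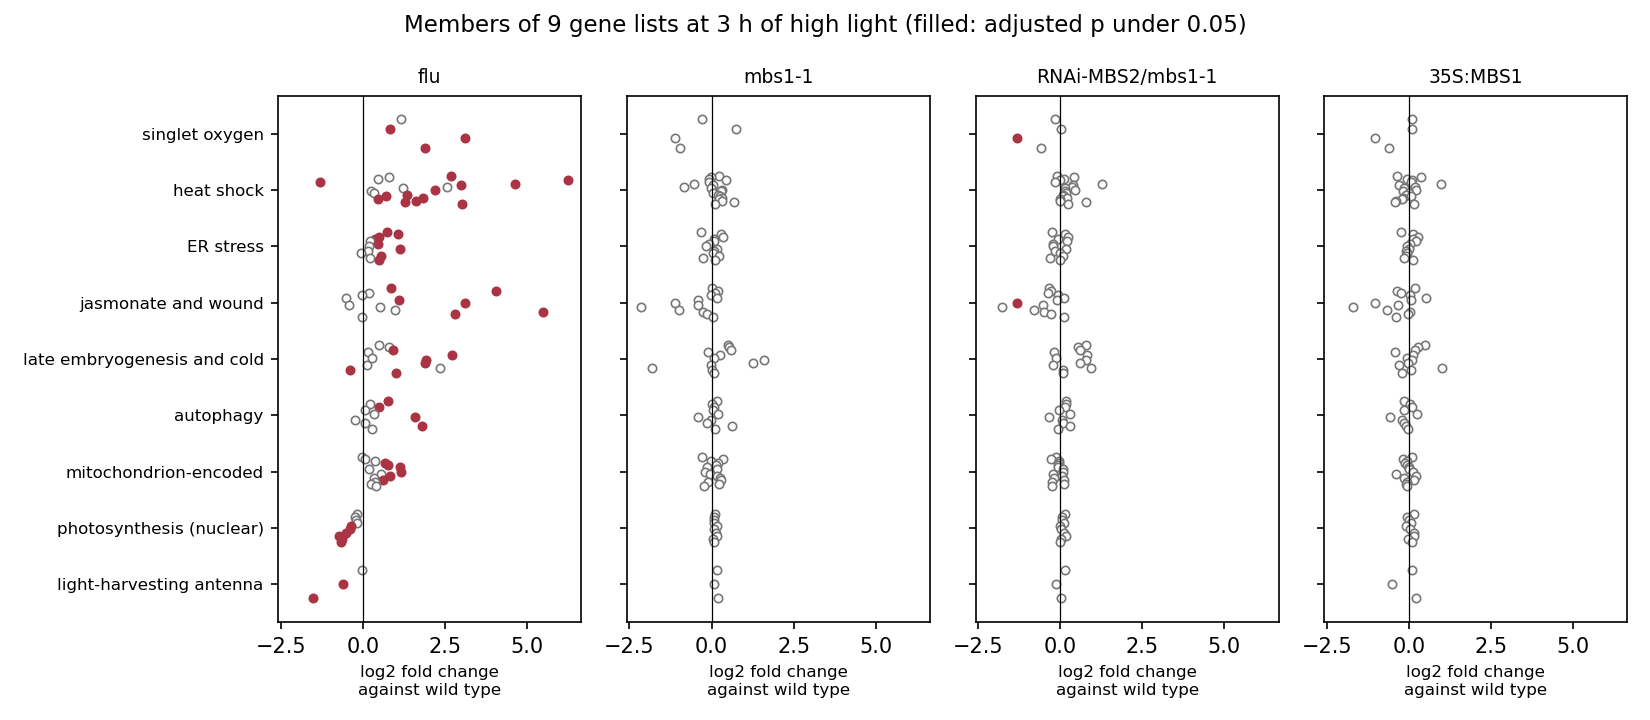
Log2 fold changes (horizontal axis, log2 of the line over wild type at 3 h) of the measured members of 9 gene lists (vertical axis), 1 point per gene and 1 panel per line, filled where the adjusted p was under 0.05. In the flu panel 8 of 13 endoplasmic reticulum stress genes, 6 of 13 jasmonate and wound genes and 3 of 4 singlet oxygen genes lie to the right of 0 and pass, while in 35S:MBS1 no member of these lists passed.

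Whether flu answered high light otherwise than wild type was tested as the difference of their 3 h against 0 h changes. AT1G52560 was raised more in flu by 6.56 ± 0.84 (adjusted p = 1.45e-05), AT2G38240 by 4.66 ± 0.75 (adjusted p = 0.000223) and ATHSP22.0 by 4.57 ± 1.09 (adjusted p = 0.00825). These sizes depended on single arrays. Wild type at 0 h stood at 5.82 ± 1.87 for AT1G52560, with 7.93 in replicate 3, and at 4.63 ± 2.83 for ATHSP22.0. Without that replicate the differences of AT1G52560, ATHSP22.0 and AT5G37670 were smaller by over 1.5-fold, and that of AT2G38240 moved as far without flu 0 h replicate 2 or flu 3 h replicate 3. AT5G61590 (-2.19 ± 0.37), AT3G52070 (-2.18 ± 0.34) and TRY, a repressor of trichome formation (-2.14 ± 0.47), had the lowest differences. Arrays of AT3G52070 went from 9.74 to 10.43 at 0 h to 6.49 to 7.40 at 3 h in flu. Wild type had only 5.59 to 6.81 and then 5.20 to 5.32. The lines with altered MBS1 went from 9.50 to 10.36 to 7.48 to 8.12, so its fall was not particular to flu. Whether the wild type signal lay above background was not tested. CML37 (3.35 ± 0.37), CML38 (1.89 ± 0.44) and AT5G64870 (1.60 ± 0.36) made 3 of 4 singlet oxygen genes respond more in flu, also 3 over the list alone (adjusted p = 0.000128, and adjusted p = 0.0573 with an estimated correlation). Of the heat shock chaperones 3 of 5 did so, also 3 over the list alone, among them AT5G37670 (3.09 ± 0.60) and HSA32 (2.29 ± 0.33), at an adjusted p of 0.000742 (adjusted p = 0.158 with an estimated correlation). LHCB4.3, which rose from 7.18 ± 0.23 to 10.29 ± 0.14 in wild type and from 7.30 ± 0.25 to 8.78 ± 0.09 in flu, had a difference of -1.62 ± 0.24. It was the 1 of 3 antenna genes that passed, with 2 over the list alone (adjusted p = 0.0194, and adjusted p = 0.125 with an estimated correlation). Of the 3 cold genes COR47 passed (1.42 ± 0.28) and 2 did over the list alone (adjusted p = 0.00699, and adjusted p = 0.148 with an estimated correlation). Of the added lists, endoplasmic reticulum stress (6 of 13 higher, adjusted p = 4.83e-05) and late embryogenesis and cold (5 of 12 higher, 2.91e-05) kept their calls with an estimated correlation (adjusted p = 0.00458 and 0.0428).

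In all, 1912 probe sets passed this test of the difference, 1167 with a higher and 745 with a lower response in flu. The share of higher ones was 61.0%, 48.0% of 2342 calls after quantile normalization and 43.9% of 2374 after centring each array on its median, so that which direction held more calls depended on the scaling. With only the 12 compared arrays in the fit the count was 1077, and there ATHSP22.0 lost its call (adjusted p 0.00216 to 0.0893 over all settings).

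**Figure D2:**
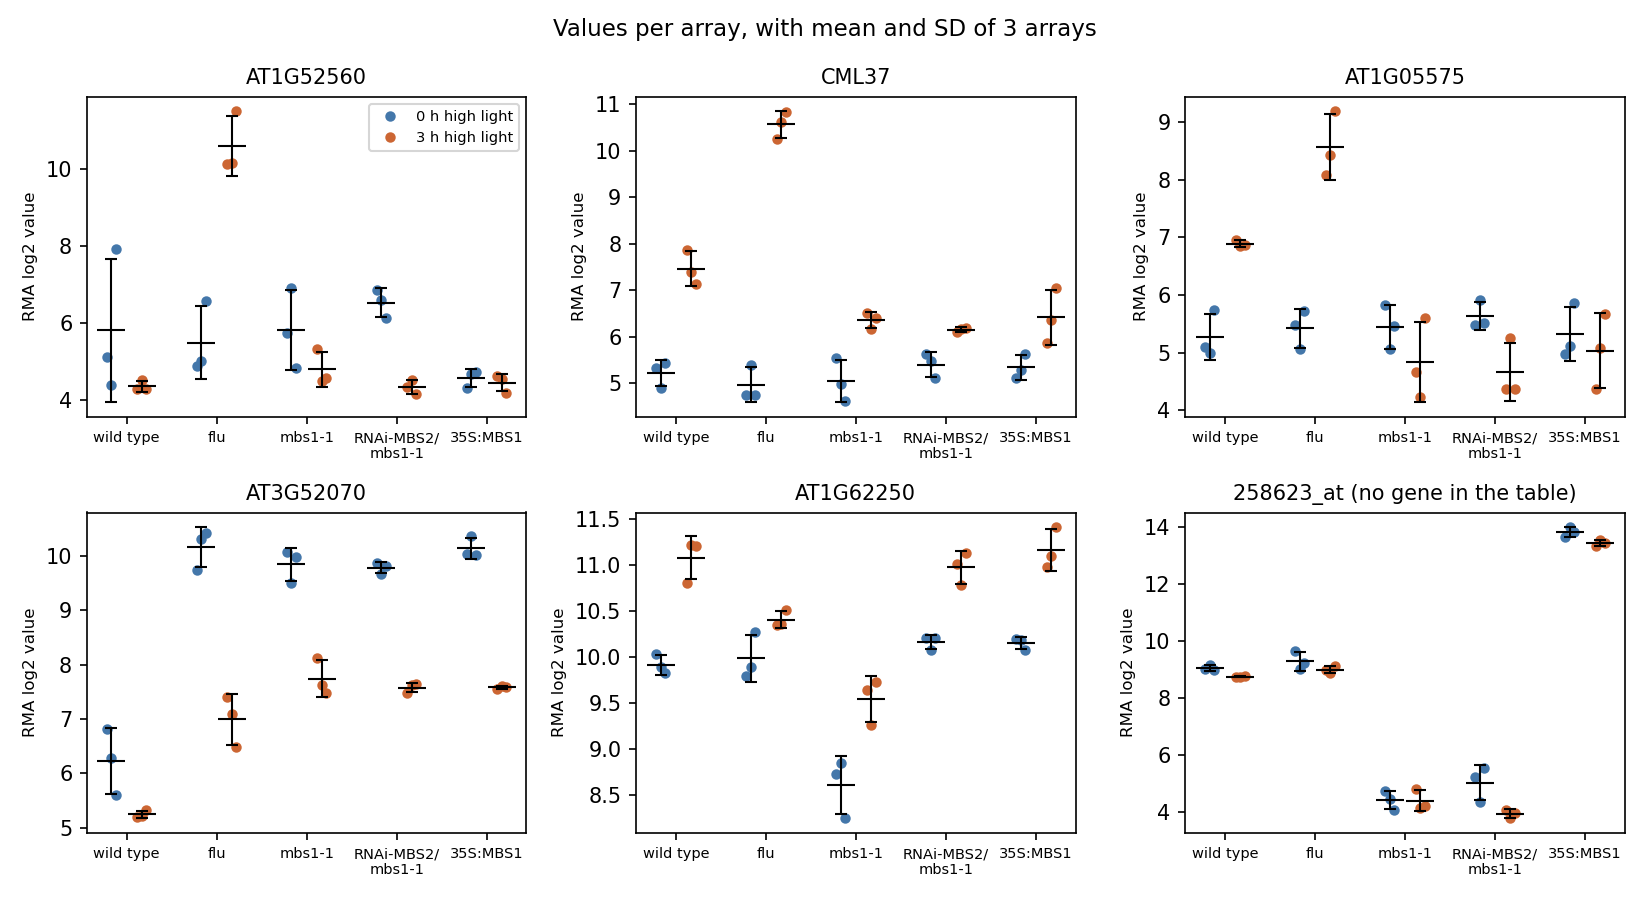
RMA log2 level (vertical axis) of AT1G52560, CML37, AT1G05575, AT3G52070, AT1G62250 and the unnamed probe set probe-258623_at in 5 lines (horizontal axis), 1 point per array in blue for 0 h and orange for 3 h, with the mean and SD of 3 arrays. CML37 at 3 h reached 10.57 in flu, 7.47 in wild type and 6.36, 6.16 and 6.42 in mbs1-1, RNAi-MBS2/mbs1-1 and 35S:MBS1.

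The comparison of mbs1-1 with wild type at 3 h asked what loss of MBS1 changed under high light. AT3G52070 was higher (2.50 ± 0.24, adjusted p = 1.43e-06), as were AT4G11710 (1.78 ± 0.39), the glutathione transferase gene GSTU28 (1.67 ± 0.24, adjusted p = 0.00114), at 8.03 ± 0.04 against 6.37 ± 0.69, ARLA1B (1.61 ± 0.26) and AT1G07590 (1.46 ± 0.31). AT1G05575 was lower (-2.05 ± 0.35, adjusted p = 0.00572), at 4.84 ± 0.70 against 6.89 ± 0.05, with SUFE2, a gene of iron-sulfur cluster assembly (-1.89 ± 0.34), AT3G23550 (-1.76 ± 0.37), AT1G62250 (-1.54 ± 0.16, adjusted p = 4.25e-06) and AT3G48640 (-1.53 ± 0.32). AT1G62250 was not lower in RNAi-MBS2/mbs1-1, which carries the same mutation, where its arrays read 10.78 to 11.13 at 3 h against 10.81 to 11.23 in wild type. The singlet oxygen list stood lower (adjusted p = 0.0399, and adjusted p = 0.327 with an estimated correlation), with none of 4 genes past the test over all probe sets. Over the list alone 2 were lower and 1 higher, and CML37 had a value of -1.11 ± 0.26 (adjusted p = 0.0502).

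There were 99 calls between mbs1-1 and wild type at 3 h, 64 higher and 35 lower, 53 of them by at least 1. The share of higher calls was 64.6%, 48.2% after quantile normalization and 55.6% after centring on the median. The count fell to 16 without mbs1-1 3 h replicate 1, the array with the highest mean, 46 without mbs1-1 replicate 2, 56 without wild type replicate 1 and 23 without wild type replicate 2. AT3G52070, AT1G62250, GSTU28 and ARLA1B passed whichever single array was left out. The last 3 of these lost their calls with the compared arrays alone in the fit (2.92e-07 to 0.0537, 6.06e-06 to 0.11 and 0.00146 to 0.0635 over all settings). AT1G05575 did not without mbs1-1 replicate 1, SUFE2 and AT3G23550 not without mbs1-1 replicates 1 or 2 or wild type replicate 2, AT3G48640 not without those or wild type replicate 1, and AT4G11710 and AT1G07590 not without any mbs1-1 array or wild type replicates 2 or 3. Over all settings the adjusted p ran from 0.00112 to 0.0702 for AT1G05575, 0.00446 to 0.108 for SUFE2, 0.0197 to 0.179 for AT3G23550, 0.0147 to 0.179 for AT3G48640, 0.0243 to 0.179 for AT1G07590 and 0.0152 to 0.228 for AT4G11710.

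RNAi-MBS2/mbs1-1 was compared in the same way. AT3G52070 (2.33 ± 0.24, adjusted p = 5.76e-06), GSTU28 (1.35 ± 0.24, adjusted p = 0.0114), ARLA1B (1.24 ± 0.26), AT4G31875 (1.16 ± 0.23) and AT1G13130 (0.99 ± 0.21) were higher at 3 h. AT1G05575 (-2.22 ± 0.35, adjusted p = 0.00289), AT3G02840 (-2.07 ± 0.41), AT5G46295 (-1.58 ± 0.33), AR781 (-1.47 ± 0.24) and AT5G05300, a gene for an IDA-like signal peptide (-1.44 ± 0.21), were lower. CML37 was the 1 of 4 singlet oxygen genes that passed, over all probe sets and over the list alone, at 6.16 ± 0.05 against 7.47 ± 0.37 in wild type (-1.31 ± 0.26, adjusted p = 0.0225). That list stood lower at an adjusted p of 0.0311 (adjusted p = 0.327 with an estimated correlation). The abscisic acid and cold list stood higher (adjusted p = 0.00086, and adjusted p = 0.129 with an estimated correlation), with none of 3 genes past the test over all probe sets, 2 over the list alone and COR47 at 0.61 ± 0.20. The heat shock chaperone list also stood higher (adjusted p = 0.0393, and adjusted p = 0.501 with an estimated correlation), with none of 5 genes past the test over all probe sets or over the list alone and HSA32 at 0.45 ± 0.23.

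Of the 50 calls of RNAi-MBS2/mbs1-1 at 3 h, 15 were higher and 35 lower, and 32 changed by at least 1. Higher calls were 30% of them, and 40.7% after centring on the median. The count was 17 without RNAi-MBS2/mbs1-1 3 h replicate 1, 13 without its replicate 3, 21 without wild type replicate 1, 17 without wild type replicate 2 and 113 without wild type replicate 3. AT3G52070, AT1G05575 and AT5G05300 passed whichever array was left out. AR781 did not without RNAi-MBS2/mbs1-1 replicate 3, GSTU28, AT4G31875 and AT3G02840 not without replicates 1 or 3 of that line or replicates 1 or 2 of wild type, and CML37 not without any array of that line or wild type replicates 1 or 2. AT5G46295 lost its call without the same arrays as CML37, ARLA1B without any array of that line or wild type replicates 2 or 3, and AT1G13130 without replicates 2 or 3 of that line or replicates 1 or 2 of wild type. The adjusted p over all settings ran from 0.00031 to 0.089 for AR781, 5.4e-05 to 0.164 for GSTU28, 9.24e-05 to 0.241 for AT4G31875 and 0.00267 to 0.261 for AT3G02840. It ran from 0.0108 to 0.231 for CML37, 0.0082 to 0.332 for AT5G46295, 0.0252 to 0.35 for ARLA1B and 0.0124 to 0.327 for AT1G13130.

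Set directly against mbs1-1 at 3 h, RNAi-MBS2/mbs1-1 differed in 2 probe sets, both higher. One was that of AT1G62250 (1.44 ± 0.16, adjusted p = 6.78e-05, and 5.74e-06 to 0.0713 over all settings), at 10.98 ± 0.18 against 9.54 ± 0.25. Wild type arrays at 3 h read 10.81 to 11.23 for this gene, so that RNAi-MBS2/mbs1-1 lay near wild type and mbs1-1 below both. Whether knock-down of MBS2 offsets an effect of MBS1 on it was not tested. The other was probe-247223_at, which has no single gene and was chosen after its values were seen (1.04 ± 0.18, adjusted p = 0.0445, and 0.00159 to 0.422 over all settings). Its call was lost without mbs1-1 3 h replicates 2 or 3 or any RNAi-MBS2/mbs1-1 array at 3 h, and the count was 1 without RNAi-MBS2/mbs1-1 3 h replicates 1 or 3. The median of all probe sets was -0.11 in this comparison, and AT1G62250 stood 1.54 above it. The heat shock chaperone list passed (adjusted p = 0.00273, and adjusted p = 0.735 with an estimated correlation) with 0 of 5 genes past limma's test over all probe sets or over the list alone, where 2366 probe sets had an unadjusted p under 0.05.

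Few probe sets were called between 35S:MBS1 and wild type at 3 h. AT3G52070 (2.34 ± 0.24, adjusted p = 5.37e-06) and the unnamed probe-258623_at were higher, and AT5G05300 (-1.20 ± 0.21, adjusted p = 0.0415) and the unnamed probe-245250_at (-1.52 ± 0.27, adjusted p = 0.0415), chosen after its values were seen, were lower. AT1G05575, called lower in both mbs1-1 lines, stood at 5.03 ± 0.65 in 35S:MBS1 against 6.89 ± 0.05 in wild type without passing. Both lower calls were lost after quantile normalization and after centring on the median, which left 2 calls, 100% of them higher. The count was 2 without 35S:MBS1 3 h replicates 1 or 2 or wild type replicate 2 and 57 without wild type replicate 3, where 5 were higher and 52 lower. AT5G05300 lost its call without 35S:MBS1 replicates 1 or 2 or wild type replicates 1 or 2 (adjusted p 0.00254 to 0.915 over all settings), and probe-245250_at without these or 35S:MBS1 replicate 3 (0.00168 to 0.915). No fixed list passed. Of the lists added later, 7 calmodulin-like genes (adjusted p = 0.0198) and 6 stress U-box ligase genes (0.0208) stood lower in 35S:MBS1, with no member past the test over all probe sets and an adjusted p of 0.28 for either with an estimated correlation. CML37 stood at 6.42 ± 0.59 there against 7.47 ± 0.37 in wild type. The calmodulin-like list also stood lower at 3 h in mbs1-1 (adjusted p = 0.000667) and RNAi-MBS2/mbs1-1 (0.0352), with an adjusted p of 0.148 and 0.348 when the correlation was estimated. Jasmonate and wound genes stood lower in these 2 lines (adjusted p = 0.00158 and 0.0168, and adjusted p of 0.202 and 0.348 with an estimated correlation). CML37 is a member of the singlet oxygen, calmodulin-like and jasmonate and wound lists. It was the 1 gene called in each of them in RNAi-MBS2/mbs1-1 at 3 h, so these lists are not independent. Late embryogenesis and cold genes (0.00882) and the longer heat shock list (0.0262) stood higher in RNAi-MBS2/mbs1-1, with an adjusted p of 0.348 and 0.74 when the correlation was estimated.

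The responses of the 3 lines with altered MBS1 were also tested against that of wild type. In mbs1-1 GSTU28 (2.23 ± 0.35, adjusted p = 0.0102), AT4G31875 (1.79 ± 0.32, adjusted p = 0.0287) and AT4G16400 (1.39 ± 0.24, adjusted p = 0.0262) were raised more, among 12 calls, all higher. The median of all probe sets was 0.14 there, and relative to it these genes stood at 2.08, 1.65 and 1.25. In RNAi-MBS2/mbs1-1 UGT84A1 (1.099 ± 0.20, adjusted p = 0.0359) and AT1G73920 (1.095 ± 0.21, adjusted p = 0.0455) responded more, and AT1G05575 (-2.58 ± 0.49, adjusted p = 0.0455), AT5G05300 (-1.61 ± 0.30, adjusted p = 0.0428) and the auxin-regulated gene HAT2 (-1.32 ± 0.26, adjusted p = 0.0455) less, among 12 calls, 2 higher and 10 lower. In that line the singlet oxygen list responded less (adjusted p = 0.0163), with none of 4 genes past the test, 1 over the list alone and CML37 at -1.49 ± 0.37. The abscisic acid and cold list responded more (adjusted p = 0.00997), with none of 3 past the test, 2 over the list alone and COR47 at 0.80 ± 0.28. Either list had an adjusted p of 0.246 with an estimated correlation. For 35S:MBS1 limma called 0 probe sets, with 732 at an unadjusted p under 0.05 where 1137 would be expected by chance. It called 1 without wild type 3 h replicate 3. Among these lines AT1G05575 was called in RNAi-MBS2/mbs1-1 alone. Its rise of 1.61 in wild type was missing in all of them, however. In mbs1-1 its arrays read 5.06 to 5.82 at 0 h and 4.24 to 5.60 at 3 h. In 35S:MBS1 they read 4.98 to 5.87 and 4.37 to 5.67, and in RNAi-MBS2/mbs1-1 5.48 to 5.91 and 4.37 to 5.25. The lower response of AT1G05575 was thus not particular to RNAi-MBS2/mbs1-1.

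These counts of 12 rested on single arrays. That of mbs1-1 was 4, 2 and 3 without its 0 h replicates 1, 2 and 3, and 2 and 24 without its 3 h replicates 1 and 3. It was 2, 4 and 28 without wild type 0 h replicates 1, 2 and 3, and 1 and 22 without wild type 3 h replicates 2 and 3. Not all calls of mbs1-1 were higher in every setting. Higher calls were 85.7% after quantile normalization, 13 of 22 (59.1%) without wild type 3 h replicate 3, 20 of 24 without mbs1-1 3 h replicate 3, 26 of 28 without wild type 0 h replicate 3 and 7 of 8 without wild type 3 h replicate 1. That of RNAi-MBS2/mbs1-1 was 6, 2 and 60 without its 0 h replicates 1, 2 and 3, and 0 and 2 without its 3 h replicates 1 and 3. It was 1, 5 and 22 without wild type 0 h replicates 1, 2 and 3, and 5, 1 and 47 without wild type 3 h replicates 1, 2 and 3. GSTU28 lost its call in 3 of 21 settings (adjusted p 5.13e-05 to 0.071 over all settings), which were the compared arrays alone, both brighter arrays left out and wild type 3 h replicate 2 left out. AT4G31875 lost it in 12 of 21 settings (0.00017 to 0.27), AT4G16400 in 8 of 21 (0.00188 to 0.327), UGT84A1 in 8 of 21 (0.0162 to 0.26), AT1G05575 in 13 of 21 (0.0231 to 0.213), AT5G05300 in 14 of 20 (0.00425 to 0.193), HAT2 in 16 of 21 (0.00854 to 0.313) and AT1G73920 in 17 of 21 (0.0218 to 0.245).

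Of the other fixed lists, the 11 plastid-encoded genes passed in no comparison (lowest adjusted p = 0.217), and neither did the 3 measured root markers (lowest adjusted p = 0.237). Lists with fewer than 3 measured genes were not tested as lists, and their members are given singly. In wild type after high light the clock gene GI changed by 4.01 ± 0.17, the dark-induced AT3G15450 by -5.45 ± 0.45, the light signalling gene HYH by 1.38 ± 0.14, the expansin gene EXPA8 by -3.72 ± 0.21, and the rapid stress transcription factor genes WRKY53 and STZ by 3.30 ± 0.32 and 3.09 ± 0.38. In flu against wild type at 3 h the detoxification genes GSTU25 and UGT73B5 differed by 3.13 ± 0.71 and 1.83 ± 0.27, WRKY53 by -1.29 ± 0.32, the defence gene SAG101 by 0.72 ± 0.21, the cell division gene AUR1 by -0.66 ± 0.19 and AT3G15450 by 1.54 ± 0.45. Of these genes in flu, AUR1 lost its call without flu 3 h replicate 3 or wild type 3 h replicates 1 or 2 (adjusted p 0.00423 to 0.0961 over all settings), and SAG101 without flu 3 h replicate 3 or wild type 3 h replicate 3 (0.00827 to 0.139). AT3G15450 lost its call without the same arrays as SAG101 and with the compared arrays alone in the fit (8.04e-05 to 0.191), and stood at 0.71 without wild type 3 h replicate 3. The sizes of GSTU25 in flu and AT3G15450 in wild type moved by over 1.5-fold with 1 array left out.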

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

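The differences of responses, their list tests and the leaving out of single arrays were planned, and the test of a wild type stock unlike the other lines was written before its result was seen. The use of left-out arrays to weigh an explanation, and all other tests of explanations in this part, were chosen only after the result was seen.

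A tested difference between the high light response of a line and that of wild type brought these results here. For flu there were 1912 calls, with AT1G52560 at 6.56, AT2G38240 at 4.66, ATHSP22.0 at 4.57, AT5G61590 at -2.19, AT3G52070 at -2.18 and TRY at -2.14. The list tests of that difference gave adjusted p of 0.00699 for abscisic acid and cold, 0.000742 for heat shock chaperones, 0.0194 for light-harvesting antenna and 0.000128 for singlet oxygen genes, and with an estimated correlation adjusted p of 0.148, 0.158, 0.125 and 0.0573. For mbs1-1 there were 12 calls, with GSTU28 at 2.23, AT4G31875 at 1.79 and AT4G16400 at 1.39. For RNAi-MBS2/mbs1-1 there were 12 calls, with UGT84A1 at 1.099, AT1G73920 at 1.095, AT1G05575 at -2.58, AT5G05300 at -1.61 and HAT2 at -1.32. In that line the lists of abscisic acid and cold (adjusted p = 0.00997) and singlet oxygen (adjusted p = 0.0163) also differed, either with an adjusted p of 0.246 when the correlation was estimated.

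Other splits of the same arrays were counted for these differences. For flu 5 of 100 splits, the real one included, gave at least 1912 calls, and the highest other gave 2683. All 4 others kept the 3 h arrays in their real groups, as 7 of the splits did, and the highest count among splits that regrouped the 3 h arrays was 10. The flu count thus follows the 3 h groups. For mbs1-1 2 of 100 splits and for RNAi-MBS2/mbs1-1 3 of 100 gave at least 12 calls, with 24 and 18 in the highest other. The others as large, 1 and 2 of them, also kept the real 3 h groups, and the highest count with the 3 h arrays regrouped was 3 in either line. For 35S:MBS1 all 100 gave at least the real count of 0, and the highest other gave 2.

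For a pair of groups there are only 10 splits, too few for a share under 0.05, since the smallest is 0.1. After high light the real split alone, 1 of 10, gave as many calls in each line, with 1 in the highest other for wild type, 56 for flu and 0 for mbs1-1, RNAi-MBS2/mbs1-1 and 35S:MBS1. Against wild type at 0 h the highest other gave 11 for flu (real 115), 0 for mbs1-1 (real 7) and 1 for 35S:MBS1 (real 4), each with 1 of 10 as large. For RNAi-MBS2/mbs1-1 at 0 h 2 of 10 were as large against wild type (27 against a real 7) and 2 of 10 against mbs1-1 (23 against a real 1). Counts several times the real one point to a structure of the samples. Without RNAi-MBS2/mbs1-1 0 h replicate 3 the counts were 66 against wild type and 15 against mbs1-1. Replicate numbers do not pair the arrays, and no other kind of structure was tested. At 3 h the highest other gave 5 for flu (real 4164), 6 for mbs1-1 (real 99), 2 for RNAi-MBS2/mbs1-1 (real 50), 0 for 35S:MBS1 (real 4) and 1 for RNAi-MBS2/mbs1-1 against mbs1-1 (real 2), each with 1 of 10 as large.

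At 3 h 18 probe sets were lower than wild type in both mbs1-1 and RNAi-MBS2/mbs1-1, among them AR781, HAT2, AT5G05300, AT1G72940 and AT1G05575. That number depended on single arrays. It was 7 without mbs1-1 3 h replicate 1 or wild type 3 h replicate 2, 8 without RNAi-MBS2/mbs1-1 3 h replicate 3, 60 without wild type 3 h replicate 3 and 1 with the compared arrays alone, and the medians below are those of the 18. Shared wild type arrays were tested in 35S:MBS1, where the median of the same 18 was -0.99, with 16 of them lower in sign, as that explanation predicts. In flu, set against the same wild type arrays, the median was only -0.27, with 3 of the 18 called higher and 5 lower. Flu differed from wild type in 4164 probe sets at 3 h, so its own changes may hide a shift of the shared arrays, and flu cannot decide. Loss of MBS1 was tested without the wild type arrays, as the mean of both mbs1-1 lines minus 35S:MBS1, which gave a median of -0.43 with 3 of 18 called lower, too small to decide. Outside those 3, the same wild type arrays may account for none, part or all of this overlap, and an effect of MBS1 in either direction is left open. Another reading, that overexpression and loss of MBS1 lower the same genes, cannot be told from the first with 3 wild type arrays.

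AT3G52070 was higher than wild type in every other line. The difference of its flu response from that of wild type was thus taken against a low wild type level, and the gene fell in the lines with altered MBS1 as well. Chance heights of the 3 wild type arrays of one time were argued against, since the gene was called higher at both times, on separate wild type arrays. It was so in 4 of 4 lines, but these share the wild type arrays of each time and add no independent test. The gene was also chosen for being called in every line. A wild type stock unlike all other lines was tested by counting the probe sets in which a line differed from each other line in one direction at both times. Wild type had 1, against 20 in flu, 1 in mbs1-1, 0 in RNAi-MBS2/mbs1-1 and 1 in 35S:MBS1. As wild type and 35S:MBS1 differed in only 4 probe sets at either time, the wild type count could not exceed 4. That it lay below the count of flu was therefore fixed in advance, and the comparison of counts cannot decide. The few calls against 35S:MBS1 leave little room for a broad difference large enough to be called, while smaller ones remain possible. A difference of the wild type stock at this gene alone could still be present and was not tested.

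Calls of mbs1-1 against wild type at 3 h were mostly higher, 64.6% of 99. A higher overall level of 1 mbs1-1 array was tested by leaving out mbs1-1 3 h replicate 1, which gave 43.8% of 16, as that explanation predicts, and leaving out wild type 3 h replicate 3 gave 38.2% of 144. Loss of MBS1 as the whole cause was argued against by RNAi-MBS2/mbs1-1, which carries the same mutation and had 30% higher calls. Whether knock-down of MBS2 offsets an effect of MBS1 there was not tested.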

How the results depend on the processing

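No called value of a gene given in the text with its change reversed under any alternative. The signs of COR47 in the wild type response, of LHCB4.1 in flu at 3 h and of AT3G28580 in 6 comparisons, none of them called, did turn. Which direction held more of the calls did turn with the scaling, from 61.0% higher to 48.0% and 43.9% for the difference of the flu response with quantile normalization and median centring, from 40.9% to 52.5% and 58.3% for flu at 0 h, and from 64.6% to 48.2% for mbs1-1 at 3 h and 58.0% to 49.5% for the mbs1-1 response with quantile normalization. It also turned with arrays left out. The wild type response went from 46.3% to 50.8% without wild type 0 h replicate 1 and 50.6% with both brighter arrays left out. Flu at 3 h went from 47.3% to 52.3% and 56.3% without flu 3 h replicates 1 and 3 and to 50.9% and 52.5% without wild type 3 h replicates 1 and 2. Flu at 0 h reached 54.6% without flu 0 h replicate 3 and 51.8% with both brighter arrays left out, and mbs1-1 at 3 h 43.8% without mbs1-1 3 h replicate 1 and 38.2% without wild type 3 h replicate 3. Directions of comparisons with fewer than 10 calls turned as well and are not listed. Both brighter arrays left out and the flu 0 h array of widest spread left out were chosen after seeing the data. Counts within 1.5 times that reported are taken as kept. The cause of the moved counts was not tested, except that testing only probe sets with exactly 1 gene lowers counts because fewer are tested, and that leaving out arrays or fitting the compared arrays alone leaves fewer degrees of freedom. Fewer degrees of freedom do not account for counts that rose with 1 array left out, as from 7 to 66 for RNAi-MBS2/mbs1-1 at 0 h and from 4 to 57 for 35S:MBS1 at 3 h.

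With only probe sets with exactly 1 gene, calls after high light were 5698 in wild type, 6011 in flu, 5647 in mbs1-1, 5734 in RNAi-MBS2/mbs1-1 and 5906 in 35S:MBS1. Against wild type they were 58, 2, 3 and 2 at 0 h and 2175, 48, 16 and 2 at 3 h for flu, mbs1-1, RNAi-MBS2/mbs1-1 and 35S:MBS1. RNAi-MBS2/mbs1-1 against mbs1-1 at 3 h gave 1, and the differences of responses 969 for flu, 7 for mbs1-1 and 1 for RNAi-MBS2/mbs1-1.

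With the compared arrays only, flu at 0 h gave 8, RNAi-MBS2/mbs1-1 at 0 h 2, 35S:MBS1 at 0 h 2, mbs1-1 at 3 h 2, RNAi-MBS2/mbs1-1 at 3 h 14 and 35S:MBS1 at 3 h 2, each against wild type. RNAi-MBS2/mbs1-1 against mbs1-1 gave 0 at both times, and the differences of responses 1077 for flu, 3 for mbs1-1 and 3 for RNAi-MBS2/mbs1-1.

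Quantile normalization and median centring moved RNAi-MBS2/mbs1-1 against mbs1-1 at 0 h to 3 and 2, 35S:MBS1 at 3 h to 2 and 2, the difference of the mbs1-1 response to 7 and 4 and that of RNAi-MBS2/mbs1-1 to 6 and 6. A trended and robust variance prior gave 2 for RNAi-MBS2/mbs1-1 against mbs1-1 at 0 h and 1 at 3 h, and leaving out probe sets with a mean under 5 gave 1 at 3 h. Both brighter arrays left out gave 56 for flu, 2 for 35S:MBS1 and 3 for RNAi-MBS2/mbs1-1 against mbs1-1 at 0 h, 15 for mbs1-1 at 3 h, and 1 and 4 for the differences of the mbs1-1 and RNAi-MBS2/mbs1-1 responses. Without the flu 0 h array of widest spread, mbs1-1 at 0 h gave 11, RNAi-MBS2/mbs1-1 against mbs1-1 at 0 h 2 and 35S:MBS1 at 3 h 2. With an estimated correlation 1 of 33 fixed-list calls was left.

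Replicate numbers do not pair the arrays. Arrays of one number had median correlations of -0.00713, -0.0158 and 0.0130 across groups, and 12 of 30 arrays were closest to their own number. A replicate block moved RNAi-MBS2/mbs1-1 against mbs1-1 at 3 h to 5 and the difference of the RNAi-MBS2/mbs1-1 response to 7.

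Leaving out 1 array gave 52 to 130 calls for flu at 0 h, 6 to 66 for RNAi-MBS2/mbs1-1 at 0 h, 2 to 3 for 35S:MBS1 at 0 h, 16 to 144 for mbs1-1 at 3 h, 13 to 113 for RNAi-MBS2/mbs1-1 at 3 h and 2 to 57 for 35S:MBS1 at 3 h. RNAi-MBS2/mbs1-1 against mbs1-1 gave 1 to 15 at 0 h and 1 to 2 at 3 h. The differences of responses gave 1 to 28 for mbs1-1, 0 to 60 for RNAi-MBS2/mbs1-1 and 0 to 1 for 35S:MBS1. Kept were the responses to high light (9296 to 9984 in wild type, 9991 to 10643 in flu, 9006 to 9777 in mbs1-1, 9101 to 9913 in RNAi-MBS2/mbs1-1 and 9518 to 9890 in 35S:MBS1), mbs1-1 at 0 h (5 to 10), flu at 3 h (2936 to 4201) and the difference of the flu response (1443 to 2085).

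Of 3240 values of named genes with 1 array left out, 2845 kept their side of the threshold, 389 lost and 6 gained a call. With the compared arrays only 374 of 463 kept theirs, 87 lost and 2 gained one, and with quantile normalization 445 kept, 17 lost and 1 gained. The number of arrays, and for probe sets of low signal the nearness to background, limit precision.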

Other observations

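The tests of where genes of the flu response move in other lines were written before their result was seen, and the simulations of shared wild type arrays were chosen after.

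Further lists added later moved in flu against wild type at 3 h. Of 15 genes encoded in the mitochondrion 6 were higher, among them nad9 (1.17 ± 0.20), nad6 (1.14 ± 0.17) and cox2 (0.83 ± 0.24), which encode parts of the respiratory chain (adjusted p = 7.16e-05, and adjusted p = 0.164 with an estimated correlation). The call of cox2 was lost without flu 3 h replicate 3 or wild type 3 h replicate 1 (adjusted p 0.00603 to 0.0761 over all settings). Of 43 UDP-glucosyltransferase genes 14 were higher and 3 lower, led by UGT73B4 (2.98 ± 0.41) and UGT76E12 (2.87 ± 0.38), at an adjusted p of 0.000205 (adjusted p = 0.164 with an estimated correlation). Of 10 autophagy genes 4 were higher, with ATG8H at 1.79 ± 0.19 and ATG8E at 1.59 ± 0.23 (adjusted p = 0.000161, and adjusted p = 0.164 with an estimated correlation). From 0 h to 3 h, 8 of these 10 genes fell in flu and 2 rose, so that most fell there as in wild type.

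One hypothesis was that genes higher in the flu response are ones that high light lowers in other lines, and the reverse. Of the 1167 calls higher in flu, 33.0% fell and 36.9% rose after high light in the mean of RNAi-MBS2/mbs1-1 and 35S:MBS1, against 32.7% and 24.9% of the 20834 probe sets without a call, which argues against it. Of the 745 calls lower in flu 47.1% rose and 30.9% fell, against 24.9% and 32.7% of those without a call. The share that rose was thus higher than among probe sets without a call. It stayed under the share set beforehand for the reverse, and calls higher in flu also rose more often (36.9%), so the reverse is left undecided.

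The lines were compared with the same wild type arrays at 3 h, which raises correlations between their differences. These were 0.629 for mbs1-1 and RNAi-MBS2/mbs1-1 (covariance 0.0352), 0.435 for mbs1-1 and 35S:MBS1 (0.0209) and 0.624 for RNAi-MBS2/mbs1-1 and 35S:MBS1 (0.0268). With flu they were 0.0968 for mbs1-1 (0.0123), 0.166 for RNAi-MBS2/mbs1-1 (0.0187) and 0.00551 for 35S:MBS1 (0.000534). In 200 simulated draws with no difference but shared controls the median correlation was 0.536, with a range of 0.000458 to 0.758, and the mean covariance 0.0200, with a highest of 0.0421. All observed correlations and covariances lie within these ranges, but the ranges are too wide to exclude much. The draws also took arrays of all groups as controls. The SD of an array's deviations from its group means was up to 0.299, in flu 0 h replicate 3. In the wild type 3 h arrays, the real shared controls, it was only 0.155 to 0.174. The simulated covariances may thus be too high for these controls, and this comparison cannot decide. In the fit to all arrays mbs1-1 and RNAi-MBS2/mbs1-1 shared 9 higher and 18 lower calls, against 0.0422 and 0.0539 if independent. The highest shared counts in 100 simulated draws were 0 and 3. These draws held only the compared groups, which leaves fewer degrees of freedom, so they cannot be set against the 9 and 18. With 1 array left out the shared calls of these lines ran from 2 to 15 higher and from 7 to 60 lower. With the compared arrays alone there was 1 of either, the lower one within the simulated highest of 3 and the higher one above that of 0. Flu shared 40 higher and 10 lower calls with mbs1-1 (5.54 and 3.38 if independent) and 10 and 13 with RNAi-MBS2/mbs1-1 (1.299 and 3.38), and 7 and 4 calls had opposite directions. The values if independent leave out the shared controls. The 3 wild type arrays cannot be split, so part or most of the excess over the values if independent may come from the shared controls. The median of -0.99 in 35S:MBS1 for the 18 shared lower probe sets also leaves this open.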
